A study of Mus musculus with 13 samples.

How the data were processed

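Gene expression was measured on 13 Affymetrix whole-transcript arrays, 1 per sample, in 6 groups. Total RNA was extracted with Qiagen RNeasy, then amplified, fragmented and labelled with NuGEN Ovation V2 and Encore reagents, per the labels' protocols. Per the submitters' processing notes the values were made with RMA, which summarises and normalizes probe intensities between arrays, and its version is not given in the sources used here. The deposited values are intensities on a linear scale, as their range shows (3.35 to 17698, with array medians from 68.3 to 80.5), although RMA itself gives log2 values, and how the authors came to linear values is not given in the sources used here. The design written before the data were examined assumed log2 values. Its stated fallback for linear values was applied, log2(intensity + 1), and 16 in place of the 1 was an alternative. The RMA background step and the number of arrays set the precision, and low intensities carry background, so differences of dim genes are understated.

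The file holds 34760 probe sets. The platform table lists 22961 of them, of which 21640 name 1 gene and 1321 name several, and 11799 are not listed and so unnamed here. Probe sets with several genes were left out. Of the 1-gene probe sets 21553 matched the gene reference by Entrez identifier and 0 symbols changed. This gave 19937 genes, and for the 954 genes with more than 1 probe set the set with the highest mean over all arrays was used, with the mean of all sets as an alternative. No coordinates are given because the sources used here name no genome build. The file has 0 columns without a sample.

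Differences were fitted with limma 3.58.1 in R 4.3.3 as a model of the 6 group means over all 13 arrays, so that the small groups share 1 estimate of the spread (7 residual degrees of freedom, with 3.08 prior degrees of freedom from empirical Bayes moderation). Tests were two-sided with Benjamini-Hochberg adjustment over all 19937 genes at 0.05. There are 4 main comparisons and 5 secondary ones, listed by the groups they contrast. Lists of genes, 36 in all, for pathways and for the cell types that skin or a sort of it can hold, were fixed before the data were examined and tested with limma's camera at its preset correlation and again with an estimated correlation, adjusted over the 36 lists. Several genes belong to more than 1 list. Counts of list members past the threshold are given over all genes and adjusted over the list alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.

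Genes were named by a rule fixed before the data were examined. In each main comparison these were the 10 largest increases and 10 largest decreases among genes with adjusted p under 0.05, an absolute log2 difference of at least 1 and no overlap between the arrays compared. Members of the lists, and Braf, Cdkn2a and Stk11, could also be named. Probe sets for small RNAs such as Mir211 and Snora20 cover a host transcript or precursor and not the mature RNA alone, and the amplification does not select small RNA.

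The fit was tested on simulated data made from the real gene means and residual spreads of 19937 genes with 200 changed. For day 50 against day 19 it recovered 62.7% of genes changed by a log2 value of 1, 83.6% at 2 and 98.5% at 3. For the Braf comparison the shares were 50.7%, 86.6% and 97%, for the melanoma genotypes 47.8%, 88.1% and 97%, and for the melanomas against the proliferations 74.6%, 95.5% and 98.5%. Of all calls 4.68%, 7.14%, 3.12% and 7.25% were false in that order, against a nominal 5%. The simulation gave each gene the same spread in every group. In the real data the SD across genes between replicates was 0.703 for the day 50 pair and 0.292 for the Cdkn2a/Braf day 19 pair. The simulated shares therefore do not give the error rates of the real comparisons. Groups of unequal spread and correlated genes were not simulated.

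Alternatives written before the data were examined were median centring, quantile normalization, the mean of probe sets, filters on dim genes (above the median level, or log2 above 6 in 2 arrays), an intensity trend with robust moderation, array weights, fits on arrays of the same material or of the compared groups, the replicate number as a block, the other pseudocount, and leaving out each array in turn. Scaling each array to a common interquartile range was added after the data were seen, because the range over genes differed between groups. Replicates of a group were compared with each other first, and no pair held identical values throughout.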

Results

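The series profiled messenger RNA in mouse melanocytes and in the lesions that arise from them, on 13 whole-transcript Affymetrix arrays. The genotypes combine an oncogenic Braf allele with loss of the tumour suppressor Cdkn2a, which encodes inhibitors of cell cycle kinases and of Mdm2, and of Lkb1, the kinase encoded by Stk11 that activates AMPK and so restrains mTORC1. Melanocytes sorted by flow cytometry came from Cdkn2a/Braf skin at day 19, before growth arrest by the labels (2 arrays), from Cdkn2a/Braf skin at day 50, after growth arrest (2 arrays), and from Cdkn2a-only skin at day 19 with wild-type Braf (2 arrays). Uncultured tissue came from Cdkn2a/Braf melanoma (2 arrays), Cdkn2a/Braf/Lkb1 melanoma (2 arrays) and pooled Lkb1/Braf melanocytic proliferations (3 arrays). The labels call the samples of each group biological replicates, and the number of arrays limits the precision of every value. Levels are log2(intensity + 1), differences are on that log2 scale with their standard error (SE), and 19937 genes were tested in every comparison. Where the lower of 2 levels is dim, the difference understates the change, and orders by size are of measured values.

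The targeted genes were examined in every group. Stk11 averaged 8.11 ± 0.35 (SD, n = 2) in Cdkn2a/Braf/Lkb1 melanoma and 8.76 ± 0.19 (SD, n = 2) in Cdkn2a/Braf melanoma, a difference of -0.65 (SE 0.39) that did not pass the test (limma adjusted p = 0.396). In the Lkb1/Braf proliferations Stk11 averaged 8.23 ± 0.14 (SD, n = 3). Cdkn2a lay between 6.23 in Cdkn2a-only cells and 6.59 in day 50 cells, and none of the comparisons called it. Braf was lower in day 50 than in day 19 Cdkn2a/Braf cells by -0.72 (SE 0.13, limma adjusted p = 0.00328), and than in Cdkn2a-only cells by -1.20 (SE 0.13, limma adjusted p = 2e-04). In the melanomas it was higher than in the proliferations by 0.29 (SE 0.10, limma adjusted p = 0.0377). Where the probes of these 3 genes lie relative to the altered part of each allele is not given in the sources used here, so these levels do not check the genotypes.

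Sorted Cdkn2a/Braf melanocytes at day 50 had lower melanocyte lineage, lysosomal and amino acid supply transcripts than at day 19. Of the 22 lineage genes measured, 16 fell and none rose, with a median difference of -1.28. Rab38, a GTPase of melanosome transport, fell by 3.67 (SE 0.30), Slc45a2, a melanosomal transporter, fell by 2.98 (SE 0.17), and Mc1r, the melanocortin receptor, fell by 3.03 (SE 0.22). Among 23 lysosome and TFEB genes 17 fell, including the cathepsins Ctsl (-3.13, SE 0.44) and Ctsb (-1.78, SE 0.20). Among 21 ATF4 and amino acid genes 10 fell, including Asns, the asparagine synthetase (-4.06, SE 0.27), and the transporters Slc7a11 (-4.61, SE 0.52) and Slc7a5 (-3.55, SE 0.22).

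The lineage list passed the camera test in the comparison of day 50 with day 19 (adjusted p = 5.51e-11), and 17 of its genes were lower when adjusted over the list alone. Its call was lost with adjusted p = 0.241 with an estimated correlation. The fall was uneven across the lineage. Tyr, the rate-limiting enzyme of melanin synthesis, was lower at -3.14 (SE 0.59) and Gpr143 at -3.86 (SE 0.33). Mitf, the lineage transcription factor, was lower at -0.52 (SE 0.17). Dct differed by -0.42 (SE 0.27, limma adjusted p = 0.245) and Tyrp1 by -0.36 (SE 0.20, limma adjusted p = 0.185). The lysosome list (median -1.01, adjusted p = 1.4e-09, 18 genes lower adjusted over the list alone) held with adjusted p = 0.0489 with an estimated correlation. So did the ATF4 list (median -0.60, adjusted p = 0.000127, 10 genes lower adjusted over the list alone; adjusted p = 0.0489 with an estimated correlation). Scaling every array to a common interquartile range left the lineage median at -0.31 (adjusted p = 0.383), the lysosome median at -0.56 (adjusted p = 0.183) and the ATF4 median at -0.33 (adjusted p = 0.183), so these calls ended. The log2 interquartile range over genes was 1.94 and 1.93 on the day 50 arrays and 2.58 and 2.54 on the day 19 arrays.

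**Figure D1:**
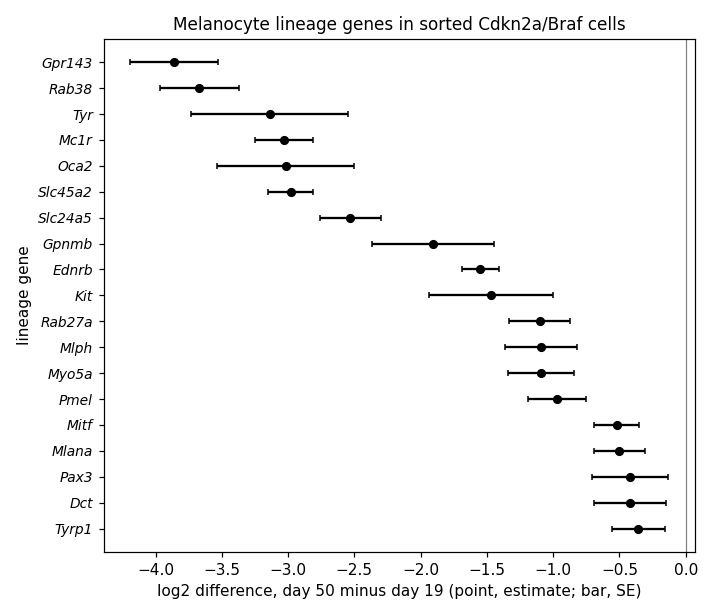
Log2 difference (day 50 minus day 19, horizontal axis) of each lineage gene with a day 19 mean above 9 in sorted Cdkn2a/Braf cells, points with SE bars. The differences run from -3.86 for Gpr143 to -0.36 for Tyrp1.

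Genes of other skin cells were higher in the sorted day 50 cells. Of 16 fibroblast genes 9 rose and 1 fell (median 1.17, 12 higher and 1 lower adjusted over the list alone), led by the collagen-binding proteoglycans Lum (4.83, SE 0.52) and Dcn (3.14, SE 0.30), while Dpt fell by 2.58 (SE 0.67). Of 14 endothelial genes 8 rose (median 1.11, or 0.52 without day 50 replicate 1; 11 adjusted over the list alone), including Pecam1 (2.36, SE 0.23). Of 19 keratinocyte genes 5 rose (median 1.55, 5 adjusted over the list alone), including Trp63, the epidermal transcription factor (1.81, SE 0.39), and Krt15 (2.69, SE 0.68). The camera adjusted p was 7.73e-05 for fibroblast, 0.000806 for endothelial and 0.0339 for keratinocyte genes. The fibroblast call was lost with adjusted p = 0.271 with an estimated correlation, the endothelial call with adjusted p = 0.353 with an estimated correlation and the keratinocyte call with adjusted p = 0.7 with an estimated correlation. The keratinocyte call ended without day 19 replicate 2 and without day 50 replicate 2.

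Antigen presentation and stress genes also rose between day 19 and day 50. Of 10 MHC class I genes 6 rose (median 0.70, 6 adjusted over the list alone), among them the immunoproteasome subunit Psmb8 (2.61, SE 0.50). Of 23 interferon response genes 7 rose (median 0.35, 7 adjusted over the list alone), among them Ifit3 (1.90, SE 0.38). Of 23 immediate early genes 9 rose (median 0.71, 9 adjusted over the list alone), including Atf3 (2.35, SE 0.26) and Fosb (2.09, SE 0.42), a response that tissue dissociation is known to induce. Camera adjusted p was 0.00432, 0.0191 and 0.00832 in that order. None held, with adjusted p = 0.277 for MHC class I, adjusted p = 0.316 for interferon and adjusted p = 0.551 for immediate early genes with an estimated correlation. Scaling to a common interquartile range ended the interferon call.

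Metabolic and signalling lists were lower at day 50. Of 24 PI3K, AKT and IGF genes 11 fell and 1 rose (median -0.65, or -0.25 without day 50 replicate 1), with Irs1 at -2.50 (SE 0.29), Akt2 at -1.90 (SE 0.26) and Igf1 at 2.04 (SE 0.50). Of 27 oxidative phosphorylation genes 13 fell (median -0.53), and of 23 glycolysis and HIF1 genes 8 fell and 2 rose (median -0.19, or -0.01 without day 50 replicate 2), with Hk2, a hexokinase, at -2.50 (SE 0.25). Of 21 sterol and fatty acid genes 6 fell (median -0.33), including Acaca (-1.77, SE 0.22), and of 23 LKB1 and AMPK genes 6 fell and 1 rose (median -0.16, or 0.01 without day 50 replicate 2), including the LKB1 partners Strada (-1.26, SE 0.19) and Stradb (-1.45, SE 0.20). Adjusted over the list alone, 13, 15, 10, 6 and 6 genes of these lists were lower. Camera adjusted p was 0.00432, 2.84e-06, 0.0191, 0.00974 and 0.0377, and none held with an estimated correlation, at adjusted p = 0.277, 0.241, 0.277, 0.299 and 0.299. Quantile normalization ended the calls of the PI3K, glycolysis, sterol and LKB1 lists, and scaling to a common interquartile range turned the oxidative phosphorylation median to 0.40, the glycolysis median to 0.04 and the test direction of the sterol and LKB1 lists.

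Of 29 cell cycle genes 3 fell at day 50, Mad2l1 (-2.96, SE 0.49), Cks2 (-3.13, SE 0.80) and Kif11 (-1.73, SE 0.49), with 2 lower adjusted over the list alone and a list median of -0.26 (camera adjusted p = 0.0377; adjusted p = 0.755 with an estimated correlation). Of 26 DNA replication genes 2 fell, Gins1 (-0.96, SE 0.29) and Ccne2 (-1.10, SE 0.36), with 0 adjusted over the list alone (median -0.32, camera adjusted p = 0.0377; adjusted p = 0.697 with an estimated correlation). Of 23 MAPK output genes 7 fell, including the feedback phosphatases Dusp4 (-2.18, SE 0.40) and Dusp6 (-1.07, SE 0.30), with 10 lower adjusted over the list alone (median -0.19, camera adjusted p = 0.0377; adjusted p = 0.277 with an estimated correlation). Each of these 3 calls ended in several alternatives, among them the filter on genes above the median level, and scaling to a common interquartile range turned the MAPK output median to 0.13. The growth arrest and senescence list was not called (median 0.26, camera adjusted p = 0.876, with a test direction opposite to its median), though Btg2 (1.80, SE 0.37) and Igfbp7 (1.45, SE 0.43) rose and Glb1, Cdkn2c and Rbl2 fell. The p53 target list (median -0.14, camera adjusted p = 0.76) and the secretory inflammatory list (median 0.24, camera adjusted p = 0.685) were not called either. The remaining lists were a hair shaft list, lower at median -0.34 (adjusted p = 0.0231; adjusted p = 0.495 with an estimated correlation), a B cell list at 0.41 (adjusted p = 0.0424; adjusted p = 0.353 with an estimated correlation), and a ribosomal protein list at -0.20 (adjusted p = 0.017; adjusted p = 0.277 with an estimated correlation). The hair shaft call ended in 6 of 15 alternatives and the B cell call in 7 of 14. Scaling to a common interquartile range turned the ribosomal protein median to 1.31. Not called were Schwann cell genes (median 1.04, camera adjusted p = 0.0721, though called as higher in 7 of 15 alternatives), neural crest genes (0.39, camera adjusted p = 0.295), WNT genes (-0.22, camera adjusted p = 0.429), CREB and SIK targets (0.15, with a test direction opposite to the median, camera adjusted p = 0.855), let-7 targets (0.27, camera adjusted p = 0.876), MHC class II (0.37, camera adjusted p = 0.55). The same held for the macrophage (-0.03), neutrophil (0.33), T and NK cell (0.32), mast cell (0.36), adipocyte (0.42), skeletal muscle (0.31) and erythrocyte (0.38) lists.

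Across all genes 2211 rose and 2884 fell from day 19 to day 50. The largest increases outside the lists were Akr1c18 (4.39, SE 0.55), Snora20 (4.23, SE 0.79), Ly6e (3.68, SE 0.23), and 2310067E19Rik (3.56, SE 0.84). Next came Cav1 of caveolae (3.44, SE 0.20), Prelp (3.38, SE 0.20), Emb (3.37, SE 0.37), Ptn (3.35, SE 0.56) and Gbp9 (3.30, SE 0.31). The largest decreases were Atg4a, an autophagy protease (-6.01, SE 0.95), Bex1 (-5.11, SE 0.55), B3galt5 (-5.02, SE 0.28), Atp6v0d2, a proton pump subunit (-4.96, SE 0.30). Next came Tmem255a (-4.80, SE 0.24), the lysyl hydroxylase Plod2 (-4.73, SE 0.17), Slc7a11 (-4.61, SE 0.52), Npy (-4.60, SE 0.27), Slc7a8 (-4.55, SE 0.43) and Pla2g7 (-4.34, SE 0.37). The median difference of all genes was 0.17, and 0.07 after median centring. Median centring of each array gave 1034 higher and 3263 lower genes, and 1835 genes were called without day 19 replicate 1, 2232 without day 19 replicate 2 and 1502 when the fit held only the 6 sorted arrays. The 2 day 50 arrays differed from each other with an SD of 0.703 across genes, against 0.292 for the day 19 pair. Sex was not balanced in this comparison, with Xist high on 2 of 2 day 50 arrays and on 1 of 2 day 19 arrays.

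Cdkn2a/Braf and Cdkn2a-only melanocytes at day 19 differ in the Braf allele by their labels, at an age before growth arrest. Genes downstream of MAPK were higher with the allele, with Ccnd1, cyclin D1, rising by 1.42 (SE 0.18) and Myc by 1.82 (SE 0.25). The MAPK output list had a median of 0.48, 2 of 23 genes passed over all genes, and 5 were higher adjusted over the list alone. Dusp6 differed by 1.40 (SE 0.30, limma adjusted p = 0.121), Spry2 by 0.86 (SE 0.19, limma adjusted p = 0.157) and Etv5 by 2.09 (SE 0.85, limma adjusted p = 0.633). The list passed the camera test (adjusted p = 2.29e-09) and held with adjusted p = 0.0232 with an estimated correlation.

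Among individual genes 47 rose and 11 fell with the Braf allele, and 1446 had an unadjusted p under 0.05. The largest increases were Pla2g7 (3.97, SE 0.37), the carbonic anhydrase Car2 (3.54, SE 0.34), the peptide transporter Slc15a1 (3.28, SE 0.24), Krtap6-1 (3.27, SE 0.36), Prkg2 (3.23, SE 0.39), and Anxa1 (3.01, SE 0.41). Next came Gabrb2 (3.00, SE 0.17), the inflammatory protease Casp1 (2.78, SE 0.30), Krtap6-2 (2.71, SE 0.21) and Gm10228 (2.55, SE 0.38). The largest decreases were Fndc1 (-2.49, SE 0.34), Mir186 (-2.21, SE 0.27), Mir211, which lies within the melanocyte gene Trpm1 (-2.20, SE 0.19), and Stxbp5l (-1.96, SE 0.31). Next came Mir18 (-1.78, SE 0.25), Platr8 (-1.59, SE 0.21), Zfp867 (-1.47, SE 0.22), Zdhhc15 (-1.46, SE 0.19), Rbms1 (-1.17, SE 0.16) and Snora31 (-1.06, SE 0.15). Trpm1 itself differed by -1.72 (SE 0.34, limma adjusted p = 0.0882). Asns was higher by 2.18 (SE 0.27), and Cdkn2b, a cell cycle inhibitor, differed by 1.07 (SE 0.19, limma adjusted p = 0.0607).

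Ribosomal protein genes had a list median of 0.24 in the Braf comparison with 0 of 23 genes past the threshold and 0 adjusted over the list alone (camera adjusted p = 4.04e-08; adjusted p = 0.0375 with an estimated correlation). The lineage list was slightly lower, at a median of -0.19, with 0 of 22 genes past the threshold over all genes and 1 lower adjusted over the list alone (camera adjusted p = 0.00201; adjusted p = 0.969 with an estimated correlation). The p53 target list was higher, at a median of 0.23 with 0 of 18 genes past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.493 with an estimated correlation), a call that ended in 4 of 15 alternatives. The lineage call ended without Cdkn2a/Braf day 19 replicate 2. Growth arrest and senescence genes (median 0.15, camera adjusted p = 0.0716), cell cycle genes (median -0.03, camera adjusted p = 0.469) and keratinocyte genes (median 0.05, camera adjusted p = 0.469) were not called. Nor were hair shaft and inner root sheath genes (median 0.13, camera adjusted p = 0.407). The keratin-associated genes Krtap6-5 (2.47) and Krtap19-2 (2.09) rose, as did Krtap6-1 and Krtap6-2. Whether the content of hair cells in the sort differed between the 2 genotypes was not tested. Only Gabrb2 passed when the fit held the 6 sorted arrays (1 gene), and 10 genes were called without Cdkn2a/Braf replicate 2, 32 without Cdkn2a/Braf replicate 1 and 32 without Cdkn2a-only replicate 2.

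Adding Lkb1 loss to Cdkn2a/Braf melanoma went with higher cell cycle, DNA replication, macrophage and secreted inflammatory transcripts. The cell cycle list had a median of 1.39, with 6 of 29 genes past the threshold over all genes, among them Cdc20, an activator of the anaphase-promoting complex (1.53, SE 0.23), Birc5 (1.79, SE 0.30) and the mitotic kinase Plk1 (1.52, SE 0.30), and 27 higher adjusted over the list alone. Of 26 DNA replication genes 3 rose, Tyms, the thymidylate synthase (1.47, SE 0.20), Ccne1 (1.03, SE 0.20) and Mcm3 (1.44, SE 0.31), with 13 adjusted over the list alone and a median of 0.82 (0.42 without Cdkn2a/Braf replicate 2). Of 21 secretory inflammatory genes 7 rose (median 1.00, or 0.64 without Cdkn2a/Braf/Lkb1 replicate 2; 9 adjusted over the list alone), including Plaur, the urokinase receptor (1.91, SE 0.15), Il1b (2.26, SE 0.49) and the collagenase Mmp13 (2.57, SE 0.55). Of 15 macrophage genes 3 rose, Fcgr3 (1.42, SE 0.20), Ms4a7 (1.72, SE 0.26) and Cd68 (1.65, SE 0.30), with 7 adjusted over the list alone and a median of 0.85.

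Camera adjusted p between the melanoma genotypes was 4.31e-18 for cell cycle, 5.01e-12 for DNA replication, 1.1e-07 for secretory inflammatory and 1.61e-06 for macrophage genes. The cell cycle, DNA replication and secretory calls were lost with adjusted p = 0.264 with an estimated correlation, and the macrophage call with adjusted p = 0.302 with an estimated correlation. The mean of the cell cycle list was 7.96 and 6.80 on the Cdkn2a/Braf melanoma arrays and 8.49 and 8.94 on the Cdkn2a/Braf/Lkb1 arrays, and without Cdkn2a/Braf replicate 2 the median difference was 0.77. The log2 interquartile range over genes was 2.45 and 2.53 on the first pair and 2.89 and 2.71 on the second.

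**Figure D2:**
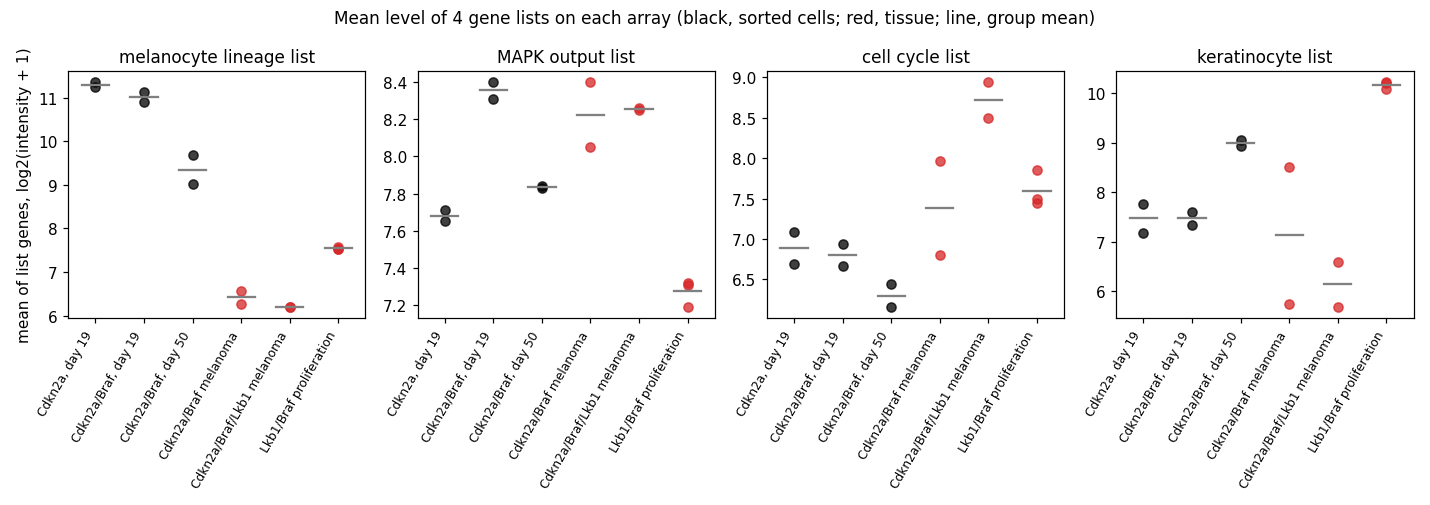
Mean log2(intensity + 1) of 4 gene lists on each of the 13 arrays, 1 point per array, with a grey line at each group mean. The keratinocyte mean is 8.51 on Cdkn2a/Braf melanoma replicate 2 and 5.74 on replicate 1.

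Other cell type markers differed between the melanoma genotypes as well. Mast cell genes were lower in Cdkn2a/Braf/Lkb1 melanoma (median -1.05), with Mcpt4, a mast cell protease, falling by 2.71 (SE 0.53), 1 of 8 past the threshold and 6 lower adjusted over the list alone. Schwann cell genes were lower (median -0.73), with Cdh19 falling at -4.97 (SE 0.70), 1 of 9 past the threshold and 5 lower adjusted over the list alone. MHC class II genes were higher (median 0.73, and 0.42 to 1.7 under the alternatives), with H2-Eb1 (2.46, SE 0.22) and H2-DMa (2.04, SE 0.38) rising, 2 of 8 past the threshold and 2 adjusted over the list alone. T and NK cell genes had a median of 0.30 (-0.07 with the filter on genes above the median level) with Cd4 rising (0.98, SE 0.21), 4 adjusted over the list alone, and fibroblast genes a median of 0.34 with Col1a1 rising (1.39, SE 0.17), 2 adjusted over the list alone. Camera adjusted p was 0.000114, 0.0017, 0.00081, 0.00798 and 0.0187 in that order, and with an estimated correlation adjusted p = 0.324, 0.264, 0.264, 0.264 and 0.375. Keratinocyte genes had a median of -0.96 with 0 of 19 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.021; adjusted p = 0.621 with an estimated correlation), which turned to 0.39 without Cdkn2a/Braf replicate 2. Without that array the mast cell call ended (median -0.31). The fibroblast call ended in 5 of 15 alternatives, among them quantile normalization, and the keratinocyte call also without Cdkn2a/Braf/Lkb1 replicate 1.

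Smaller shifts with Lkb1 loss in melanoma were found in the interferon list (median 0.25, camera adjusted p = 0.0225; adjusted p = 0.333 with an estimated correlation), where Irf7 (0.78, SE 0.13) and Oas1a (0.73, SE 0.16) rose, and in oxidative phosphorylation (median 0.24, camera adjusted p = 0.0012; adjusted p = 0.302 with an estimated correlation). Sterol genes had a median of 0.25 (camera adjusted p = 0.00737; adjusted p = 0.302 with an estimated correlation), ATF4 genes 0.18 (camera adjusted p = 0.0302; adjusted p = 0.264 with an estimated correlation), p53 targets 0.32 (camera adjusted p = 0.0312; adjusted p = 0.302 with an estimated correlation) and glycolysis genes 0.11 (camera adjusted p = 0.0312; adjusted p = 0.302 with an estimated correlation). Quantile normalization ended the interferon, sterol, ATF4, p53 and glycolysis calls. Scaling to a common interquartile range turned the oxidative phosphorylation median to -0.22, and the filter on genes above the median level turned the p53 median to -0.14. Not called were the lineage list (median -0.26, camera adjusted p = 0.336), MAPK output (-0.05, camera adjusted p = 0.393), LKB1 and AMPK (0.03, camera adjusted p = 0.973), CREB and SIK targets (-0.07, camera adjusted p = 0.526). The same held for let-7 targets (0.06, camera adjusted p = 0.336), WNT (camera adjusted p = 0.299), neutrophil (0.09, camera adjusted p = 0.0703), adipocyte (0.06, camera adjusted p = 0.336), skeletal muscle (0.23, camera adjusted p = 0.469) and erythrocyte genes (-0.07, camera adjusted p = 0.61). Hair shaft (-0.17, camera adjusted p = 0.0798), PI3K (-0.22, camera adjusted p = 0.184), growth arrest (-0.08, camera adjusted p = 0.336), lysosome (0.13, camera adjusted p = 0.247), MHC class I (0.11, camera adjusted p = 0.308), B cell (0.12, camera adjusted p = 0.535), endothelial, neural crest, ribosomal protein and immediate early genes were not called either. Single members of lists that were not called still passed, including the MAPK target Fosl1 (1.67, SE 0.28), the ERK inhibitor Spry2 (-0.88, SE 0.19), Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27 (-1.11, SE 0.21), Pik3r1 (-0.87, SE 0.15), Tnc (2.10, SE 0.26) and the imprinted gene Peg10 (1.79, SE 0.28).

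Across all genes 364 rose and 146 fell in Cdkn2a/Braf/Lkb1 melanoma. The long noncoding RNA AI506816 rose from a dim level of 4.03, so its difference (6.89, SE 0.40, and 5.95 to 7.27 under the alternatives) may understate the change. Other large increases were Brinp3 (3.54, SE 0.33), Cd209f (3.12, SE 0.51), the collagenase Mmp1a (3.11, SE 0.44), and Trim30d (3.09, SE 0.17). Next came Glipr1 (3.07, SE 0.30), Ramp3 (3.06, SE 0.17), the natriuretic peptide Nppb (2.68, SE 0.31), 1700012B09Rik (2.67, SE 0.23) and Moxd1 (2.63, SE 0.47). The largest decreases were Gdpd3 (-5.09, SE 0.56), Cdh19, the flavin monooxygenases Fmo2 (-4.48, SE 0.61) and Fmo1 (-3.51, SE 0.68), and Dmp1 (-3.64, SE 0.36). Next came the transporters Abca8a (-3.53, SE 0.57) and Abca8b (-2.95, SE 0.40), Aox3 (-3.08, SE 0.51), Pcdh20 (-3.04, SE 0.37) and the laminin Lama2 (-2.86, SE 0.55). The count was 135 without Cdkn2a/Braf replicate 2, the split was 379 higher and 358 lower without Cdkn2a/Braf replicate 1, and scaling to a common interquartile range gave 189 higher and 130 lower.

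Both melanoma genotypes together were compared with the Lkb1/Braf proliferations, which carry the Braf allele and Lkb1 loss without loss of Cdkn2a. Pigment genes were lower in the melanomas. Of 22 lineage genes 14 fell and 2 rose (median -1.0, 14 lower and 2 higher adjusted over the list alone), with Dct at -4.89 (SE 0.21), Mlana at -3.45 (SE 0.15), Tyrp1 at -3.33 (SE 0.15) and Pax3, a neural crest transcription factor, at 1.71 (SE 0.22). MAPK output genes were higher (median 1.08), with 14 of 23 rising and 2 falling and 15 higher adjusted over the list alone, including Ccnd1 (2.18, SE 0.14), Dusp4 (2.16, SE 0.31) and Spry4 (1.95, SE 0.22). Neural crest and invasive genes were higher (median 1.18), with 17 of 27 rising and 2 falling over all genes and adjusted over the list alone, including Tnc (3.2, SE 0.20), Sox2 (2.81, SE 0.23), Cdh2, N-cadherin (2.96, SE 0.27), and Axl (1.28, SE 0.14).

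Camera adjusted p between the melanomas and the proliferations was 8.76e-06 for lineage, 1.66e-05 for MAPK output and 3.73e-06 for neural crest genes. These calls were lost with adjusted p = 0.302 for the lineage list, adjusted p = 0.0763 for MAPK output and adjusted p = 0.116 for the neural crest list with an estimated correlation. Scaling to a common interquartile range ended the neural crest call. The samples are tissue of mixed cells. Whether a differing cell content gave the MAPK output and neural crest differences was not tested.

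Epidermal, hair and fat genes were much lower in the melanomas than in the proliferations, and muscle genes were lower with wide differences between arrays. All 19 keratinocyte genes fell (median -3.44, 19 adjusted over the list alone), with Krt5 at -5.00 (SE 0.78) and Krt15 at -5.01 (SE 0.52). All 21 hair shaft and root sheath genes fell (median -1.87, 21 adjusted over the list alone), with Krt25 at -5.67 (SE 0.45) and Tchh at -5.52 (SE 0.35). Of 9 adipocyte genes 8 fell (median -1.71, 9 adjusted over the list alone), with Adipoq at -4.54 (SE 0.47). Of 14 skeletal muscle genes 5 fell (median -2.13, 5 adjusted over the list alone), with Myh4 at -3.39 (SE 0.93). The mean of the muscle list was 7.30, 10.41 and 10.20 on the proliferation arrays, and 7.92, 6.17, 6.39 and 8.44 on the melanoma arrays. Camera adjusted p was 2.48e-10, 2.61e-16, 2.62e-06 and 0.00382 in that order, and with an estimated correlation adjusted p = 0.302, 0.0763, 0.256 and 0.634. Xist, transcribed from the inactive X chromosome, was lower by -6.13 (SE 1.37) and the Y-linked Eif2s3y higher by 4.45 (SE 1.06). Xist was high on 3 of 3 proliferation arrays and on 0 of the 4 melanoma arrays, so the sex of the animals differed with the groups.

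Stromal and metabolic lists also differed between the mean of the melanoma groups and the proliferations. Of 14 endothelial genes 8 rose (median 0.63, 11 adjusted over the list alone), including Cdh5, VE-cadherin (2.04, SE 0.36). Of 15 macrophage genes 6 rose (median 0.88, 6 adjusted over the list alone), including Csf1r (1.27, SE 0.24). Of 21 secretory inflammatory genes 10 rose and 4 fell (median 0.73, 10 and 4 adjusted over the list alone), including Plau, urokinase (2.33, SE 0.39). Of 21 sterol and fatty acid genes 14 fell and 1 rose (median -0.60, 14 and 1 adjusted over the list alone), including Hmgcs1 (-1.31, SE 0.18) and Scd1 (-2.41, SE 0.54). Of 24 PI3K, AKT and IGF genes 9 rose and 1 fell (median 0.40, 12 and 1 adjusted over the list alone), including Igf1r (1.56, SE 0.22). Of 23 lysosome genes 10 rose (median 0.46, 11 higher and 1 lower adjusted over the list alone), including Sqstm1 (0.99, SE 0.16). Of 27 oxidative phosphorylation genes 12 rose (median 0.34, 12 adjusted over the list alone), including Sdha (0.93, SE 0.21). Camera adjusted p was 0.000608, 0.032, 0.0346, 0.000136, 0.0153, 0.00382 and 0.00187 in that order, and with an estimated correlation adjusted p = 0.397, 0.634, 0.473, 0.256, 0.302, 0.302 and 0.302. The macrophage call ended in 8 of 18 alternatives and the secretory call in 10 (median 0.31 without Cdkn2a/Braf/Lkb1 melanoma replicate 2). The macrophage mean was 8.70 and 8.67 on the Cdkn2a/Braf melanoma arrays, within the 8.40 to 8.76 of the proliferation arrays. On the Cdkn2a/Braf/Lkb1 arrays it was 9.87 and 9.51. The secretory mean was 6.94 and 6.77, 6.52 to 6.79, and 7.71 and 8.17 in that order. For these lists the Cdkn2a/Braf melanomas thus overlapped the proliferations. Quantile normalization ended the macrophage, secretory, PI3K and lysosome calls and turned the oxidative phosphorylation median to -0.09. Scaling to a common interquartile range turned that median to -0.57 and the test direction of the lysosome list, whose median was then 0.06.

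Some lymphoid genes were lower in the melanomas, with Jchain, of plasma cells, falling at -3.74 (SE 0.16). Of 8 B cell genes 4 fell (median -0.40, 6 adjusted over the list alone; camera adjusted p = 0.00295; adjusted p = 0.302 with an estimated correlation). Of 16 T and NK cell genes 4 fell (median -0.24, 3 adjusted over the list alone; camera adjusted p = 0.0467; adjusted p = 0.302 with an estimated correlation), a call that ended in 7 of 18 alternatives, with medians up to 0.04. Of 10 MHC class I genes 5 fell (median -0.35, 5 adjusted over the list alone; camera adjusted p = 0.0423; adjusted p = 0.439 with an estimated correlation), a call that ended in 4 of 18 alternatives. Cell cycle genes had a median of 0.53, with 5 of 29 rising, including Cdk1 (1.25, SE 0.31), and 0 adjusted over the list alone (camera adjusted p = 0.0242; adjusted p = 0.712 with an estimated correlation). The cell cycle call ended in 9 of 18 alternatives, with medians down to 0.12. Growth arrest and senescence genes were not called (median 0.32, camera adjusted p = 0.159), though Cdkn1b (1.59, SE 0.16), Cdkn2b (1.36, SE 0.15) and Igfbp3 (2.22, SE 0.35) rose and Cdkn1c fell by 1.00 (SE 0.14). Among let-7 targets (median -0.03, camera adjusted p = 0.683) Hmga2 rose by 2.94 (SE 0.22). Not called were p53 targets (0.36, camera adjusted p = 0.0715), interferon (0.36, camera adjusted p = 0.0518), fibroblast (0.28, camera adjusted p = 0.159), DNA replication (0.11, camera adjusted p = 0.236), Schwann cell (-0.38, camera adjusted p = 0.305), MHC class II (-0.26, camera adjusted p = 0.446). The same held for erythrocyte (-0.23), ATF4 (0.16), LKB1 and AMPK (0.15), glycolysis (-0.12), ribosomal protein (0.06), mast cell (0.04), neutrophil (0.01), WNT (-0.03), CREB and SIK, and immediate early genes.

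Across all genes 4042 rose and 3724 fell in the melanomas. The largest increases were the neurofilaments Nefm (5.20, SE 0.46) and Nefl (3.63, SE 0.59), Tac1 (5.15, SE 0.51), Eif2s3y, and Sema3a (4.19, SE 0.18). Next came Upp1 (4.09, SE 0.21), Prkg2 (3.99, SE 0.30), Mmp1a (3.90, SE 0.34), the retinoic acid binding protein Crabp1 (3.88, SE 0.14) and Slc14a1 (3.69, SE 0.21). The largest decreases after Xist were Krt25, Tchh, Krt77 (-5.33, SE 0.90), Krtdap (-5.28, SE 1.28), Krt71 (-5.03, SE 0.40), Krt15, Krt5, Krtap6-2 (-4.94, SE 0.16) and Dct. Median centring gave 4850 higher and 2562 lower genes, scaling to a common interquartile range gave 5528 and 2734, and quantile normalization turned the balance to 2391 and 2679.

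Each melanoma genotype was compared with the proliferations. The cell cycle list was higher in Cdkn2a/Braf/Lkb1 melanoma (median 1.15, 16 of 29 rising, 20 adjusted over the list alone; camera adjusted p = 7.04e-06; adjusted p = 0.47 with an estimated correlation) and was not called in Cdkn2a/Braf melanoma (median -0.16, camera adjusted p = 0.233). MAPK output genes were higher in both, with medians of 0.94 and 0.86 (camera adjusted p = 4.49e-05 and 2.4e-05; adjusted p = 0.0993 and 0.0842 with an estimated correlation). In Cdkn2a/Braf/Lkb1 melanoma 3991 genes rose and 4099 fell, which median centring turned to 4802 and 2801 and scaling to a common interquartile range to 5111 and 2688. In Cdkn2a/Braf melanoma 2507 rose and 1770 fell, which quantile normalization turned to 1461 and 1743.

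Against Cdkn2a-only cells at day 19, the same 2 day 50 arrays had lower lineage genes (median -1.5, 16 of 22 falling, 18 adjusted over the list alone; camera adjusted p = 7.99e-13; adjusted p = 0.208 with an estimated correlation) and lower lysosome genes (median -0.94, 16 of 23 falling, 16 adjusted over the list alone; camera adjusted p = 4.13e-09; adjusted p = 0.105 with an estimated correlation). MAPK output genes were not called there (median 0.15, camera adjusted p = 0.763). Genotype and age differ together in this comparison, so neither can be credited alone. In total 2780 genes rose and 2774 fell, with a median of all genes of 0.19 (0.03 after median centring), which median centring turned to 869 and 3335 and scaling to a common interquartile range to 2075 and 3869.

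Comparisons of tissue with sorted day 50 cells mix stage with the kind of material, so group and material cannot be told apart. The Lkb1/Braf proliferations also differ from these cells in genotype. The Cdkn2a/Braf melanomas share their genotype but not their sex, with Xist high on 0 of 2 melanoma and 2 of 2 day 50 arrays. Lineage genes were lower than in day 50 cells in Cdkn2a/Braf melanoma (median -2.43, 20 of 22 falling, 21 adjusted over the list alone; camera adjusted p = 3.03e-14; adjusted p = 0.265 with an estimated correlation) and in the Lkb1/Braf proliferations (median -1.82, 15 falling, 16 adjusted over the list alone; camera adjusted p = 1.55e-11; adjusted p = 0.143 with an estimated correlation). Cell cycle genes were higher, with medians of 0.76 in the melanoma (10 of 29 rising, 10 adjusted over the list alone; camera adjusted p = 3.62e-05; adjusted p = 0.447 with an estimated correlation) and 1.12 in the proliferations (15 rising, 21 adjusted over the list alone; camera adjusted p = 1.23e-10; adjusted p = 0.295 with an estimated correlation). Macrophage genes were higher, at medians of 2.41 and 2.15 (camera adjusted p = 1.04e-08 and 2.45e-11; adjusted p = 0.369 and 0.143 with an estimated correlation). The melanoma comparison called 3087 higher and 3375 lower genes. With the arrays of the compared groups alone these were 468 and 38, with array weights 1571 and 426, and without melanoma replicate 2 1910 and 851. The proliferation comparison called 1817 and 1835, which median centring turned to 1637 and 3146 and scaling to a common interquartile range to 1859 and 3796.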

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

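Signal was found in probe sets that the report does not use, because the gene table does not list them and they carry no gene name here. Of these 11799 probe sets 858 changed between day 19 and day 50 (402 higher, 456 lower), 29 with the Braf allele at day 19 (4 higher, 25 lower), 7 with Lkb1 loss in melanoma (5 higher, 2 lower) and 2140 between the melanomas and the proliferations (520 higher, 1620 lower). Of the tests below, the scaling to a common interquartile range, the count of keratinocyte genes, the look at the levels at which lineage genes began or ended and the use of Pax3 and of the other cell types were chosen only after the data had been seen.

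Lineage genes were lower and markers of other skin cells higher in the sorted day 50 cells, which a change of state after growth arrest could explain, a biological alternative that was not tested. The series has no day 50 cells without the Braf allele. Age and growth arrest thus differ together between these groups and cannot be told apart. A narrower range of values on the day 50 arrays stays open for the lineage genes, because scaling to a common interquartile range left a median of -0.31 (adjusted p = 0.383) while quantile normalization left -1.03. It does not account for the keratinocyte genes, whose median was 1.55 and under the first scaling 2.31 (adjusted p = 4.55e-05), though their call ended without day 19 replicate 2, without day 50 replicate 2 and with an estimated correlation (adjusted p = 0.7). Fewer melanocytes in the sort would lower all lineage genes alike, and the interquartile range of the differences of 19 abundant lineage genes was 8.9 times their median SE (9.2 for the 18 that ended above a level of 6). The genes brightest at day 19, Dct (13.29), Mlana (13.21) and Tyrp1 (13.18), were among those that fell least, so bright signals may understate a fall. Rab38 and Pax3 began at like levels (11.15 and 11.12) and differed by -3.67 and -0.42. Gpnmb and Myo5a in the set are not specific to melanocytes. Fewer melanocytes may thus add to the fall, and as its whole cause they are less likely but not excluded. Keratinocytes among the sorted cells remain possible, since all 8 of the most abundant keratinocyte genes were positive and 1 passed the test, and a first bound of at most 4 was dropped after the value was seen because a missed threshold does not show an unchanged gene. The SE of these genes draws on the spread of all 13 arrays, tissue included. Krt10 averaged 9.15 (SD 0.20) at day 19 and 12.05 (SD 0.06) at day 50, with an SE of 1.14 for the difference. Krtdap averaged 5.24 (SD 0.74) and 9.66 (SD 2.29), with an SE of 1.68. The number that passed thus depends on the tissue arrays as well as on the sorted ones.

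Cell cycle genes were higher in Cdkn2a/Braf/Lkb1 melanoma. A wider range of values on those arrays is not the whole cause, because the median was 1.13 after scaling to a common interquartile range (adjusted p = 7.56e-12) and 1.18 after quantile normalization, though the call itself was lost with an estimated correlation (adjusted p = 0.264). A single array is not the whole cause either, because the lowest median over the 4 fits that each leave out 1 array was 0.77 and the highest 1.95. The lowest median came without Cdkn2a/Braf replicate 2. That array had higher means than replicate 1 for keratinocyte (8.51 against 5.74), mast cell (8.43 against 6.85) and Schwann cell genes (8.16 against 7.21). Its mean for skeletal muscle genes was lower (6.17 against 7.92). Whether its content of other cells lowered the cell cycle level was not tested. Loss of Lkb1 could be the biological cause, with 2 arrays per genotype to show it.

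Lineage genes were lower in the melanomas than in the Lkb1/Braf proliferations. A lower share of melanocytic cells would lower all of them, but the interquartile range of the differences of 6 abundant lineage genes was 8.7 times their median SE (6.5 for the 4 that ended above a level of 6), and Pax3 rose by 1.71 (SE 0.22). Markers of other cell types moved unequally, with endothelial genes higher (median 0.63, adjusted p = 0.397 with an estimated correlation) and keratinocyte genes lower (-3.44). The rest of the tissue thus differed in composition too, so these markers cannot tell whether the melanocytic share changed. A lower share may contribute, and the lineage genes cannot decide whether it is the whole cause. Dct and Tyrp1 ended at 5.23 and 5.06, under the level of 6, so their starting levels (10.12 and 8.39) limit their falls. Of the 4 that ended above it, Pmel ended at 6.05, and Gpnmb and Myo5a are not specific to melanocytes. The rise of Pax3, which a lower share alone would not give, is 1 gene chosen after the data were seen. Loss of pigment gene expression in the tumour cells would be the biological alternative, and Cdkn2a genotype, malignancy and sex differ together between these groups. Lkb1 loss is unbalanced too, since every proliferation array has it but the Cdkn2a/Braf melanoma arrays do not.

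Of the 35 ways to divide the 7 tissue arrays into 4 and 3, 1, the real division itself, gave as many genes (7150 in a fit of these arrays), and the highest other gave 750. Every other division puts melanoma and proliferation arrays on the same side, so few genes could pass there. The count thus shows only that the melanomas and proliferations differ, not why, and sex follows the same division. Of the 47 genes higher with the Braf allele at day 19, 32 were lower at day 50 and 1, Lgals1, was higher (0.53, SE 0.14). The comparisons share the day 19 arrays, and the covariance of their differences was -0.031 against -0.047 to -0.039 in simulations of the sharing alone. That covariance is over all genes and does not test the 47, of which 6.8 would be lower at day 50 if the calls were independent. The 47 were chosen as high on arrays that the day 50 comparison subtracts, so 6.8 is not the number that no change would give. The size of any excess is thus unknown, and part of it may come from the shared arrays.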

How the results depend on the processing

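The named genes were picked from these data for large differences without overlap between arrays. Leaving out an array could therefore not reverse them, and their steadiness does not carry over to other genes. Of the values that named genes took under the alternatives, 1125 kept their direction and their side of the threshold, 98 kept only their direction and 0 reversed. For lists the numbers were 2124 and 208, with 54 newly past the threshold and 18 reversed, and 45 counts moved by more than 1.5 times while 96 did not. The cause was not tested except where fewer genes or arrays enter a fit. Dim genes near background limit what the arrays can show. Quantile normalization gave 3066 genes for day 50 against day 19, 294 for the melanoma genotypes, 5070 for the melanomas against the proliferations, 3516 for day 50 against Cdkn2a-only cells and 4646 for Cdkn2a/Braf/Lkb1 melanoma against the proliferations, and turned oxidative phosphorylation to -0.09 in the melanomas against the proliferations. Genes above the median level gave 22 for Braf, 202, 4550, 3594 and 4433 in the order of the last 4 comparisons, 3313 for Cdkn2a/Braf melanoma and 2334 for the proliferations against day 50, and turned T and NK cell (-0.07) and p53 genes (-0.14) between the melanoma genotypes. Array weights gave 2263 for day 50 against day 19, 193 for Braf, 2011 for day 50 against Cdkn2a-only cells, 1997 and 1165 for melanoma and proliferations against day 50. Arrays of the same material gave 1502, 1 (Gabrb2), 794 for the melanoma genotypes and 1805 for day 50 against Cdkn2a-only cells, and arrays of the compared groups 506 and 1912 for melanoma and proliferations against day 50. With the replicate number as a block the counts were 21 for Braf, 259 for the melanoma genotypes and 2025 for the proliferations against day 50. Arrays with the same number did not deviate together (r from -0.117 to 0.0933, 0 of 30 over 0.1), and 2 of 13 arrays correlated best with their own number. In groups of 2 arrays the deviations mirror each other and values of r recur, so this check is weak and shows only no sign of pairing. The interquartile range scaling, chosen after the data were seen, gave 36, 319 and 5655 for the same 3 comparisons. For day 50 against day 19 it turned MAPK output (0.13), glycolysis (0.04), sterol (-0.08), LKB1 (-0.05, these 2 by the direction of their test), ribosomal protein (1.31) and oxidative phosphorylation (0.40). Between the melanoma genotypes it turned ribosomal protein (-0.51) and oxidative phosphorylation (-0.22), and against the proliferations ribosomal protein (-1.35) and oxidative phosphorylation (-0.57). There only the direction of the test, not the sign of the median, turned for glycolysis (-0.35), lysosome (0.06) and immediate early genes (-0.15). Leaving out 1 array at a time, where a lone array is assumed to vary like the other groups, gave 1835 to 5835 genes for day 50 against day 19, 10 to 57 for Braf, 135 to 737 for the melanoma genotypes, 5400 to 7358 for the melanomas against the proliferations. It gave 2740 to 6393 for day 50 against Cdkn2a-only cells (2811 without Cdkn2a-only replicate 1), 2215 to 3577 for Cdkn2a/Braf melanoma (2328 and 2837 without its replicate 2 and proliferation replicate 2) and 4343 to 7034 for Cdkn2a/Braf/Lkb1 melanoma against the proliferations. It gave 2761 to 6714 for Cdkn2a/Braf melanoma (3915 without its replicate 1) and 2317 to 4879 for the proliferations against day 50 (2396 without proliferation replicate 2). Between the melanoma genotypes the immediate early list, whose test direction turned, ranged from -0.37 (without Cdkn2a/Braf replicate 1) to 0.23, and the keratinocyte list ranged from -2.75 to 0.39.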

Other observations

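The long noncoding RNA AI506816 was high on all 5 arrays with Lkb1 loss (9.75 to 11.03) and low on the other 8 (3.37 to 4.51). It was singled out after its values were seen, by a search for genes that separate these arrays, in which 317 genes separated them, 11 of them by more than 1. Among the others were H2-Eb1, of MHC class II, higher, and Cdh19, lower. The 5 arrays with Lkb1 loss are all tissue, while 6 of the other 8 are sorted cells. Only the 2 Cdkn2a/Braf melanoma arrays thus set Lkb1 loss apart from the kind of material in this search. The levels of AI506816 on the other 8 arrays are near background, so its difference may understate the change.

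Xist was at 9.57 or more on 7 arrays and at 4.82 or less on 6. It was high on 1 of 2 arrays in each day 19 group, on 2 of 2 at day 50, on 3 of 3 proliferation arrays and on 0 of the 4 melanoma arrays, and the Y-linked genes were high on the arrays where it was low.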
